A study of Mus musculus with 2 samples.

How the data were processed

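Small RNA was sequenced from the liver of wild-type C57BL/6 mice aged 2 to 3 months that had free access to food. The labels give 1 group with 2 replicates. Total RNA was isolated with Trizol from snap-frozen tissue, and libraries were made from 1 µg with an Illumina TruSeq small RNA kit, per the labels' protocols. Sequencing was on an Illumina HiSeq instrument, per the series design text. The submitters' processing notes name cutadapt 1.5, FastQC 0.11.2 and Bowtie 1.0.1 and the mouse build GRCm38 (mm10). The program that called the miRNA loci and its filters are not given in the sources used here.

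The files deposited by the authors give whole-number read counts per called miRNA locus, not normalised, together with the position, the mature and hairpin sequences and the annotation of each locus. Replicate 1 listed 200 loci and replicate 2 listed 220. Of these, 168 and 187 carried a miRNA name. The other 32 and 33 loci had no miRNA name and held 16231 and 13608 counts, or 5.02% and 2.46% of all listed counts. They were kept out of library totals and tests. The files list called loci only, so in the main tests a miRNA missing from a library was treated as not listed, not as a count of 0. In group shares an unlisted member added nothing to the share of that library. An alternative setting treated unlisted miRNAs as 0.

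Where a mature name had several loci, the locus with the highest count was used. This gave 306351 and 538023 counts over 165 and 183 distinct names, and shares are of these totals. The sums are over listed loci, and the number of reads sequenced is not given in the sources used here. File positions counted from 0 and were raised by 1. After that shift 164 and 183 named arms lay at the position of the same miRNA in the GENCODE M21 annotation of GRCm38, and 4 arms per library were not matched.

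With 1 group, no test between conditions was possible and levels were described. Shares carry exact Clopper-Pearson 95% intervals per library and a mean ± SD over both libraries. The libraries were compared with each other by a 2-sided exact binomial test per miRNA at TMM effective library sizes, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. It covered the 131 miRNAs listed in both libraries with at least 10 counts summed. Log2 ratios are replicate 2 to replicate 1, with a prior count of 0.5. The spread between replicates was edgeR's common dispersion with an intercept-only design. No quasi-likelihood test was run, because there is no contrast between groups. The design written before the data were examined assumed that every miRNA has a value in both libraries. Restricting tests to miRNAs listed in both was decided once the files had been read.

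The lists comprised 20 fixed groups of miRNAs (hepatocyte-enriched, lipid and cholesterol, glucose and insulin, those reported to target Sirt1, Ppargc1a or Ppara, 5 miRNA families or clusters, the Dlk1-Dio3 imprinted cluster, and markers of endothelial, immune, erythroid, stellate, biliary, muscle, pancreatic and neural cells). They were fixed from general knowledge before the data were examined, as were the tests, the alternatives and the rule for naming, except where stated. The median log2 ratio of each list with 3 or more tested members was placed among 10000 random lists of the same size matched on mean log2 CPM. For arm usage, hairpins with both arms named and at least 20 counts in each library were tested against equal shares by a 2-sided exact binomial test within each library, and arm shares were compared between libraries by Fisher's exact test. The comparison of arm shares between libraries was not part of the written design. Clusters were compared by a 1-sided permutation test with 100000 resamples.

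The miRNAs named are the 15 with the highest mean level, the 2 highest listed members of each list and any member of a list of at most 4, and the 6 highest and 6 lowest log2 ratios among those past the test with at least 100 counts. They also include the 5 most counted hairpins dominated by each arm and up to 5 whose dominant arm differed between libraries, and the highest and lowest member of each cluster with 3 or more tested members. Others are named as chosen after their values were seen.

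Counts with counting error alone (Poisson) were simulated for 131 miRNAs at the real means and library sizes. On these the test between replicates called 64.8% of miRNAs changed 1.5-fold, 78.8% of those changed 2-fold and 0.955% of unchanged ones. No further spread between libraries was simulated, so these rates do not cover it. Simulated coefficients of variation of 0.1, 0.2 and 0.4 were recovered by edgeR as 0.101, 0.196 and 0.408. A list of let-7 members shifted by -0.5 lay outside the middle 95% of random lists in 5 of 10 simulated data sets. The same held for 5 of 80 unshifted lists, with the glucose and lipid lists left out. The list comparison thus detected shifts of that size only in part. The simulated log2 ratios had a smaller SD than the 0.682 of the 131 tested miRNAs, so these rates hold for the simulation only.

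Alternatives were DESeq2 size factors, library totals, no filter or at least 50 counts, other pseudocounts and prior counts, thinning, a total without the most abundant miRNA, summed loci, and each replicate alone. Treating unlisted miRNAs as 0, a total over all listed loci, summed loci for list shares, a 50-count minimum for list medians and clusters restricted to loci that lie together in both libraries were added after the data were seen. Software was R 4.3.3 with edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Reads carried no molecular identifiers that the labels describe, so intervals cover counting error only.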

Results

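The data described the small RNAs of liver from young adult C57BL/6 mice fed without restriction, in 1 group of 2 replicate libraries. The series title places them in a study of miRNAs that control metabolic master regulators. The listed loci held 323447 counts in replicate 1 and 553325 in replicate 2, of which 306351 and 538023 belonged to named miRNAs. Together the libraries listed 197 named miRNAs, of which 151 were in both and 111 had at least 10 counts in each. Nothing in the labels says that the replicates came from separate animals, so the spread between them may be technical.

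The first question was which miRNAs the fed liver contained and at what level. Levels are shares of counts, not calibrated against known amounts, and the SD leaves out any bias that both libraries share. miR-22-3p was the most abundant by a wide margin, at 33.8% ± 0.241 of named miRNA counts (SD, n = 2). It was followed by miR-92a-3p of the miR-17/92 cluster at 11.1% ± 3.22, and by miR-26a-5p at 6.19% ± 0.309. miR-122-5p, the miRNA best known as a marker of hepatocytes, ranked 8 at 2.77% ± 0.380. It had 7668 counts in replicate 1 and 16356 in replicate 2.

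The other miRNAs among the 15 most abundant belonged largely to broadly expressed families. miR-191-5p took 4.81% ± 0.135 of counts, miR-30a-5p 4.54% ± 0.668, miR-30d-5p 4.09% ± 0.538 and miR-181a-5p 3.63% ± 0.741. miR-378a-3p, encoded in an intron of Ppargc1b, took 2.25% ± 0.383, and miR-423-5p took 2.05% ± 0.116. miR-27b-3p reached 1.81% ± 0.206 and miR-10a-5p 1.63% ± 0.422. The let-7 members let-7c-5p, let-7a-5p and let-7b-5p took 2.47% ± 0.678, 2.02% ± 0.759 and 1.99% ± 0.617. The 10 most abundant miRNAs held 74.4% of counts in replicate 1 and 77.7% in replicate 2, and 22 and 19 miRNAs held 90%.

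In the annotation, miR-22-3p (AAGCUGCCAGUUGAAGAACUGU) lay at GRCm38 chromosome 11, 75463772 to 75463793, plus strand, within an exon of its host transcript Mir22hg. miR-92a-3p lay at chromosome 14, 115044476 to 115044499, in an exon of the non-coding Mir17hg. Its listed sequence had 24 bases, of which the last 2 differed from the reference in both libraries. miR-122-5p (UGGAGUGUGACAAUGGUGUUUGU) lay at chromosome 18, 65248866 to 65248888, outside protein-coding genes. miR-26a-5p was listed in an intron of Ctdspl at chromosome 9, 119031811 to 119031832. Several of these mature sequences differ little from a relative or arise from more than 1 locus, so the split between let-7a, let-7c and let-7f, between miR-30a and miR-30d, and between the loci of miR-26a, miR-92a and miR-181a is uncertain.

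**Figure D1:**
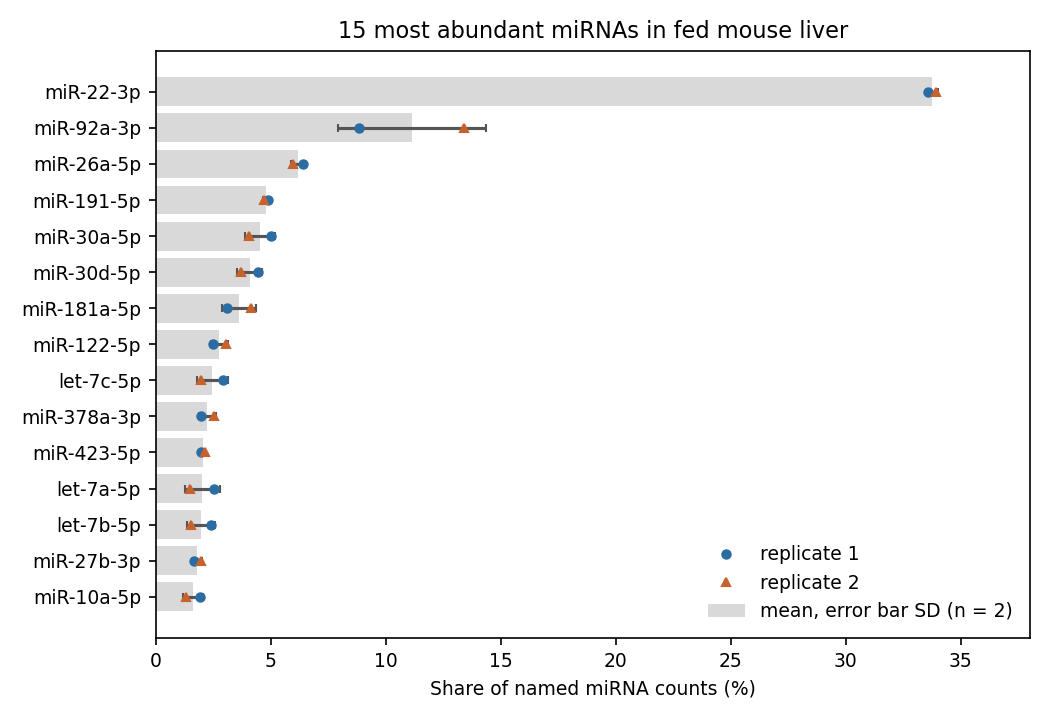
Share of named miRNA counts (percent, linear axis from 0) of the 15 most abundant miRNAs. Bars give the mean and error bars the SD of 2 libraries, and points the single libraries. miR-22-3p stands at 33.8%, against 11.1% for miR-92a-3p and 2.77% for miR-122-5p.

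The second question was how the counts divided among miRNA groups with known roles or cell types. The hepatocyte-enriched group took 4.83% of counts in replicate 1 (95% interval 4.76 to 4.91) and 5.17% in replicate 2 (5.11 to 5.22), led by miR-122-5p and miR-192-5p (1.37% ± 0.122). The group with reported roles in lipid and cholesterol handling took 4.97% ± 0.453, led by miR-378a-3p and miR-27b-3p, with 4 of its 15 members listed. The glucose and insulin group took 7.66% ± 0.455, most of it miR-26a-5p, followed by miR-29a-3p at 0.544% ± 0.0247. miRNAs reported to target Sirt1, the NAD-dependent deacetylase that acts on metabolic regulators, took 37.5% ± 0.969, nearly all of it miR-22-3p and miR-181a-5p, and the rest of the group was far lower.

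miRNAs reported to target Ppargc1a, the coactivator of mitochondrial and gluconeogenic genes, took 0.643% ± 0.116, led by miR-30e-5p (0.351% ± 0.0405) and miR-93-5p (0.118% ± 0.0301). Those reported to target Ppara, the nuclear receptor for fatty acid oxidation, took 2.07% ± 0.209. Within that group miR-27b-3p was followed by miR-21a-5p at 0.252% ± 0.00397, and miR-27b-5p stood at 0.00119% ± 0.000628. miR-21a-3p was listed in replicate 1 only, with 1 count. By family, miR-30 members took 9.89% ± 1.39, let-7 members 9.04% ± 2.31 and miR-29 members 0.554% ± 0.0259. The miR-17/92 cluster and its paralogs took 11.3% ± 3.18, of which miR-92a-3p was the bulk and miR-93-5p the next. Of the 13 members of this group, 3 were listed.

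Within the miR-29 family, miR-29c-5p stood at 0.00661% ± 0.00173, miR-29c-3p at 0.00226% ± 3.86e-05 and miR-29a-5p at 0.000583% ± 0.000561. miR-29b-3p and miR-29b-1-5p were listed in replicate 2 only, with 4 counts each. The miR-15/16 family took 0.641% of replicate 1 (95% interval 0.613 to 0.670) and 0.120% of replicate 2 (0.111 to 0.130). Its most abundant member, miR-16-5p, was listed in replicate 1 only, and miR-15b-5p stood at 0.136% ± 0.0570.

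Groups that mark other cell types were low. Immune markers took 0.277% ± 0.0910, led by miR-150-5p (0.254% ± 0.0808) and miR-146a-5p (0.0224% ± 0.0104). Stellate and mesenchymal markers took 0.454% ± 0.148, led by miR-145a-5p (0.238% ± 0.152) and miR-143-3p (0.202% ± 0.00393). The endothelial markers miR-126a-5p and miR-126a-3p stood at 0.0368% ± 0.00473 and 0.00314% ± 0.00155, and their group at 0.0399% ± 0.00629. Biliary epithelial markers took 0.0257% ± 0.00728, nearly all miR-200b-3p at 0.0249% ± 0.00757, with miR-200b-5p at 0.000768% ± 0.000298. The Dlk1-Dio3 imprinted cluster took 0.0648% ± 0.0275, led by miR-127-3p at 0.0571% ± 0.0165, and miR-434-3p was listed in replicate 2 only, with 32 counts.

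The erythroid group was listed in replicate 2 only, as 14 counts of miR-486b-5p. The neural group was listed in replicate 1 only, as 6 counts of miR-129-1-3p and 3 of miR-129-5p. No member of the muscle or the pancreatic group was listed in either library. Because the files list called loci only, an unlisted miRNA sets no upper limit on its level, and group shares count listed members alone. Replicate 1 and replicate 2 listed 1 and 5 arms of the Dlk1-Dio3 cluster. They listed 11 and 16 arms of the glucose and insulin group, and 10 and 13 of the Sirt1 group. The mean and SD of such a group compare unlike sets of arms. The lists overlap in part, for example miR-143 in the glucose and the stellate groups.

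**Figure D2:**
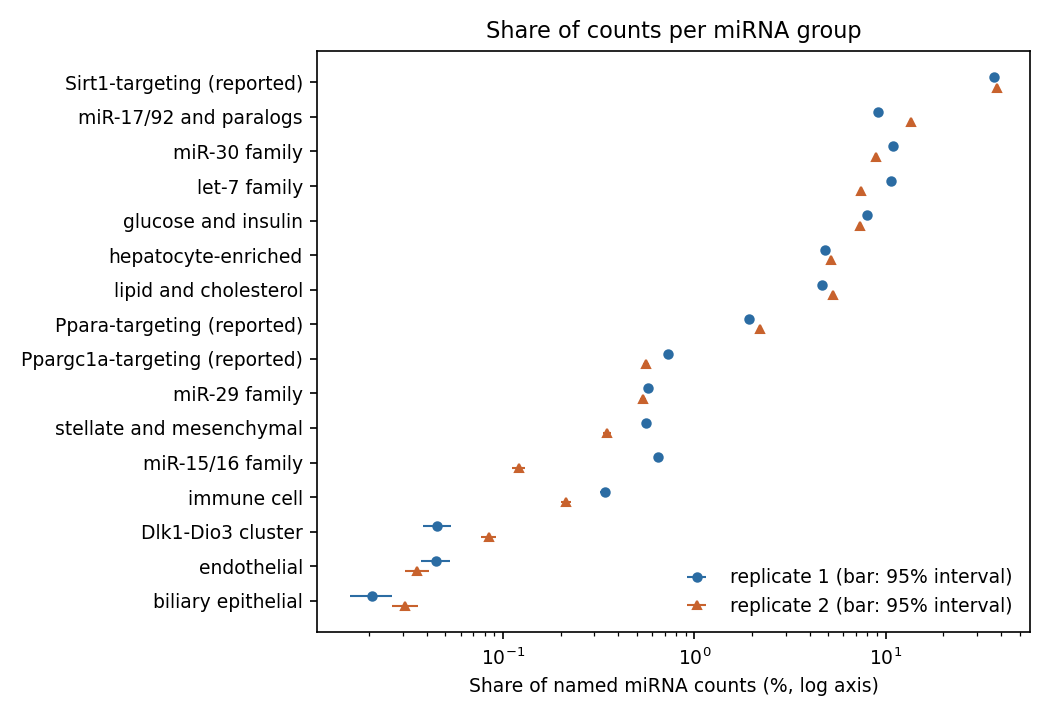
Share of named miRNA counts (percent, log axis) of the miRNA groups listed in both libraries. Points are single libraries and bars their exact 95% binomial intervals. The hepatocyte-enriched group lies at 4.83% and 5.17%, above every group of markers of other cell types.

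The third question was how far the replicate libraries differed from each other. The let-7 family was lower in replicate 2, at 7.40% of counts (95% interval 7.33 to 7.47) against 10.7% (10.6 to 10.8) in replicate 1. Of its 10 tested arms, 8 were lower in replicate 2, 1 was higher and 1 did not pass the test. The lower arms included let-7d-5p (log2 ratio -0.95) and let-7a-5p (-0.62), and the arm that was higher was let-7d-3p (0.51). The family's median log2 ratio of -0.47 ± 0.40 (SD over arms) lay at percentile 0.02 of matched random lists, and at 0.45 with at least 50 counts summed. The random lists drew miRNAs of any family, while let-7 arms are related in sequence, so these percentiles may be too extreme. With p-values adjusted over the list alone, 9 arms passed.

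Among miRNAs with at least 100 counts, the highest ratios to replicate 1 were those of miR-1948-3p (log2 ratio 1.39), miR-744-5p (1.06), miR-149-5p (0.95), miR-200b-3p (0.79), miR-92a-3p (0.76) and miR-127-3p (0.76). The lowest were those of miR-145a-5p (-1.24), let-7d-5p (-0.95), miR-146a-5p (-0.82), miR-497a-5p (-0.73), miR-15b-5p (-0.72) and miR-320-3p (-0.70). Their adjusted p-values in the exact binomial test ranged from 0.00658 for miR-497a-5p to 6.25e-71 for miR-145a-5p, with miR-92a-3p still lower. miR-145a-5p had 1060 counts in replicate 1 and 702 in the deeper replicate 2, and miR-744-5p had 621 and 2030.

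In the hepatocyte-enriched group 3 of 7 tested arms were higher in replicate 2, 1 was lower and 3 did not pass, with 4 past the test adjusted over the list alone. miR-122-5p was higher (0.44), and miR-192-5p (-0.02) and miR-194-5p (0.01) did not pass. In the glucose and insulin group 1 of 9 arms was higher, 1 was lower and 7 did not pass, with 2 adjusted over the list alone. In the lipid and cholesterol group 2 of 6 were higher, 2 lower and 2 not past the test, with 4 adjusted over the list alone. miR-378a-3p (0.51) and miR-27b-3p (0.40) were the higher arms. For the group reported to target Sirt1, 2 of 9 arms were higher, 1 was lower and 6 did not pass, with 3 adjusted over the list alone. For that reported to target Ppargc1a, 2 of 4 were lower and 2 did not pass, with 3 adjusted over the list alone. Both tested arms of the group reported to target Ppara were higher, also adjusted over the list alone.

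The miR-30 family had 4 of 7 arms lower and 3 not past the test, with 4 adjusted over the list alone, and a median log2 ratio of -0.14 ± 0.06. The miR-15/16 family had 2 of 4 tested arms lower, with 3 adjusted over the list alone, and its median of -0.72 ± 0.64 lay at percentile 2.07. With at least 50 counts summed, 2 of its arms remained, too few to place the median. For the miR-17/92 cluster and paralogs 1 of 4 arms was higher, 1 lower and 2 not past the test, with 2 adjusted over the list alone. Both tested immune arms, miR-150-5p (-0.50) and miR-146a-5p, were lower, also adjusted over the list alone. Of 5 stellate and mesenchymal arms, miR-145a-5p alone was lower and 4 did not pass. The miR-29 arms (3) and the endothelial arms (2) did not pass. Apart from let-7 and miR-15/16, the medians of the 9 other lists with 3 or more tested arms lay between percentiles 13.1 and 91.3.

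Several of these counts depended on the scaling. With library totals in place of TMM, the arms that passed were 1 higher and 3 lower in the hepatocyte-enriched group, 0 and 2 in glucose and insulin, 2 and 3 for Sirt1, 0 and 4 for Ppargc1a, 1 and 0 for Ppara, 0 and 5 in miR-30, 0 and 3 in miR-15/16, and 1 and 2 in miR-17/92. The other groups kept their counts. miR-26a-5p changed from higher (0.06) to lower (-0.10), miR-192-5p and miR-194-5p were called lower, and miR-21a-5p (0.20) was no longer called. With DESeq2 size factors only miR-30 changed, with 3 arms lower, as miR-30b-5p (-0.26) no longer passed.

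Over all 131 tested miRNAs, 58 differed between the libraries by more than counting error, 28 higher and 30 lower in replicate 2, and 22 of them by 1.5-fold or more. With library totals in place of TMM, 64 differed, 19 higher and 45 lower, as the median log2 ratio of all tested miRNAs moved from -0.03 to -0.19. The median absolute log2 ratio was 0.35, edgeR's common biological coefficient of variation was 0.229 (0.352 with DESeq2's dispersion, and 0.722 with unlisted miRNAs as 0), and log2(CPM + 1) correlated across miRNAs with Pearson's r = 0.980 and Spearman's rho = 0.981, miRNAs not being independent replicates. The test compares these 2 libraries and not conditions.

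**Figure D3:**
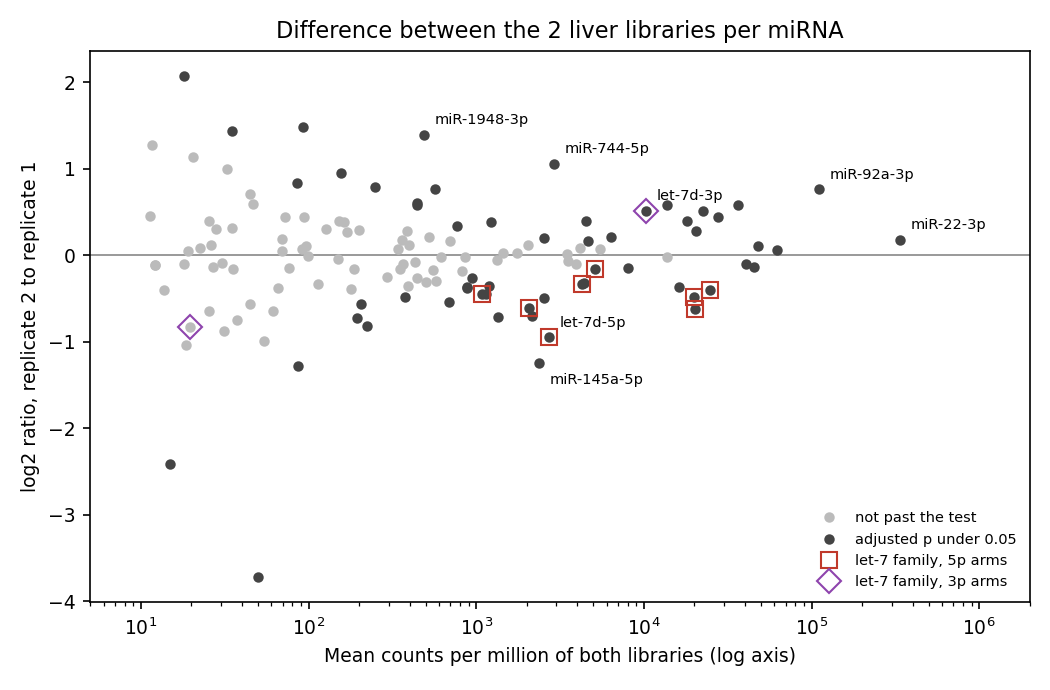
Log2 ratio of replicate 2 to replicate 1 against the mean level (CPM, log axis) for 131 miRNAs. Dark points passed the exact binomial test (adjusted p under 0.05). The let-7 5p arms (squares) all lie below 0, and of the 3p arms (diamonds) let-7d-3p lies at 0.51.

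The fourth question was which arm of each hairpin was retained. The Mir22 hairpin was dominated by its 3p arm, with 0.00772% ± 7.46e-05 of its counts on 5p (SD, n = 2), and Mir92-1 had 0.283% ± 0.134 on 5p. Mir378a (2.31% ± 0.326), Mir27b (0.0679% ± 0.0423) and Mir151 (9.69% ± 2.34) were the next most counted of the tested hairpins dominated by 3p. Among the 47 tested hairpins, the most counted ones dominated by 5p were Mir181a-2, with 99.99% ± 0.00110 of counts on 5p, and Mir30a (99.96% ± 0.00146). Mir122 (99.96% ± 0.00172), Mir423 (99.5% ± 0.0664) and Mirlet7b (99.96% ± 0.0211) followed. miR-181a-5p was listed at Mir181a-2 only, while Mir181a-1 was listed with its 3p arm alone (4 counts in replicate 1 and 6 in replicate 2). The 5p share of Mir181a-2 may thus include reads from Mir181a-1, which its SD does not cover.

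Of 47 hairpins tested, 20 were dominated by 5p and 24 by 3p in both libraries, and 35 had an arm ratio over 10-fold. Mir674 was dominated by neither arm. In Mir1843a the 5p share was 47.3% in replicate 1 (95% interval 33.7 to 61.2) and 92.5% in replicate 2 (79.6 to 98.4), and in Mir339 it was 35.1% (22.9 to 48.9) and 44.2% (35.5 to 53.2). No hairpin was dominated by opposite arms in the 2 libraries. Arm shares differed between the libraries in 4 hairpins by Fisher's exact test after adjustment, Mirlet7d, Mir151, Mir92-1 and Mir1843a. In Mirlet7d the 5p share was 28.9% (27.5 to 30.4) and 12.9% (12.1 to 13.7), with an adjusted p of 3.24e-90 by the 2-sided exact test. Mirlet7d and Mir674 were named after their values were seen.

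**Figure D4:**
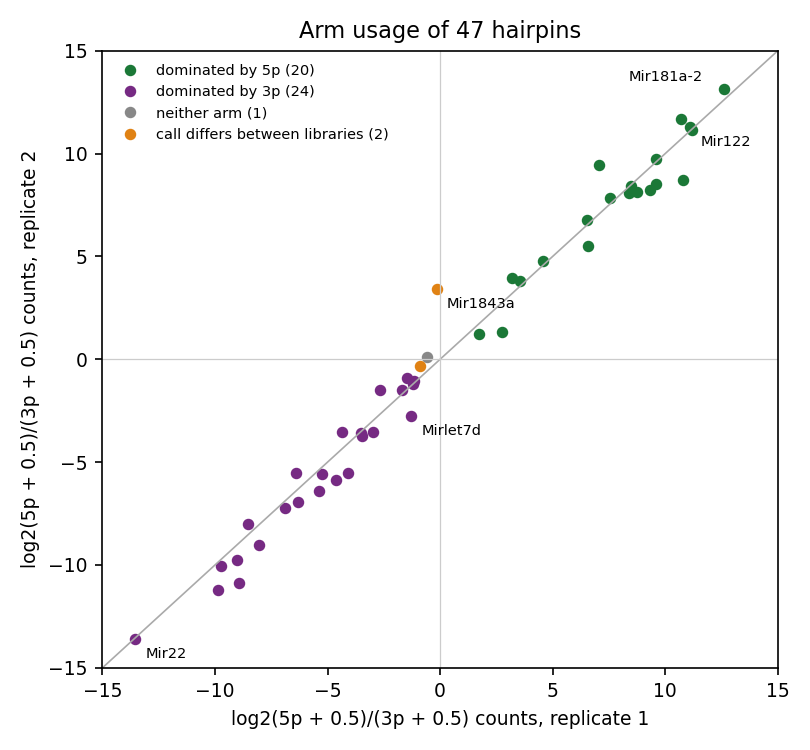
Log2 ratio of 5p to 3p counts (prior count 0.5) in replicate 1 and replicate 2 for 47 hairpins, with the line of equality. Hairpins dominated by 5p (20) and 3p (24) separate along the line, and Mir1843a lies off it.

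The fifth question was whether miRNAs of a shared primary transcript had similar levels and moved together. Members of a cluster often differed widely in level. let-7c-5p exceeded miR-99a-5p 64.3-fold and miR-30d-5p exceeded miR-30b-5p 43.5-fold in mean level. miR-145a-5p exceeded miR-143-3p in replicate 1 (1060 against 628 counts) and lay below it in replicate 2 (702 against 1073). In the cluster of miR-99b, miR-125a and let-7e, with each hairpin represented by its more abundant arm, let-7e-5p was highest at 0.108% ± 0.0319 and miR-99b-3p lowest at 0.00615% ± 0.00239. The log2 ratios between libraries of members of the same cluster differed by 0.45 on average over 12 clusters, against 0.52 for permuted members (1-sided permutation test, p = 0.184). In the cluster of miR-181a and miR-181b the locus used for miR-181b in replicate 1 lay in another cluster, and without this cluster the values were 0.42 and 0.51 over 11 clusters (same 1-sided permutation test, p = 0.126). Pairs other than those of the miR-99b cluster were chosen after their values were seen, and let-7c also has a copy at another locus.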

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

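The tests of depth for miRNAs listed in 1 library were chosen after the result was seen; those of missing hairpins and of other names were chosen before.

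Signal outside the named miRNAs lay in loci without a miRNA name. Loci in tRNA genes held 10989 counts in replicate 1 and 886 in replicate 2. A fragment from a tRNA-Gly gene at GRCm38 chromosome 1, 171044985 to 171045012, plus strand (GCAUUGGUGGUUCAGUGGUAGAAUUCUC), accounted for 10221 of the counts in replicate 1, or 3.16% of all its listed counts, and was not listed in replicate 2. Loci in rRNA held 2693 and 8181 counts, of which the gene Gm24601 had 2273 and 7860. The rRNA loci include those in Gm42418, which the files call a long non-coding RNA and RefSeq places in an 18S rRNA-related sequence. Loci in snoRNA genes held 827 and 1237 counts, led by Snord12 with 537 and 882. Loci without a small RNA annotation in the sources used held 1650 and 3265 counts, and an origin in rRNA or tRNA is not excluded for them. Loci in the Y RNA gene Rny3 held 58 and 36 counts. A snRNA locus, Rnu12, held 6 counts in replicate 1 and 1 in replicate 2. Loci overlapping the miRNA genes Mir328 and Mir6236 held 8 counts in replicate 1, and Mir6236 held 2 in replicate 2. In replicate 1 each of these classes was above the 3 counts that a count of 0 would allow. In replicate 2 the snRNA and miRNA genes were not.

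Outside the comparison of libraries stood miRNAs with at least 100 counts in 1 library that were not listed in the other. miR-16-5p had 1321 counts in replicate 1, miR-1247-5p had 118 there, and miR-365-3p and miR-425-5p had 302 and 153 in replicate 2. From the listed counts and library sizes, the smallest expected count in the lacking library was 97.6. The choice by at least 100 counts fixed a high value in advance, so an expected count of 3 or less was not possible. At the expected counts of these 4, counting error alone would very rarely leave a miRNA without reads. Over all 46 miRNAs listed once, 29 had an expected count above 3, a share that leaves open how many of the rest were missed by chance. Among the 17 of these 29 with a known other arm, that arm was also missing for 12 (8 of 13 hairpins) and listed for 5, so whole hairpins left out of a library stay open as an explanation for part of them. None of the 29 sequences stood under another name (0 of 29 by their first 15 bases), so the filters of the authors' locus calling stay open as an untested explanation, and no biological explanation was tested.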

How the results depend on the processing

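Unlisted miRNAs as 0, the total over all loci, summed loci, the 50-count minimum for medians and clusters of loci lying together were chosen after the data were seen. With 1 group, no paired analysis was possible. Of 626 alternative values, 554 stayed within the replicate spread or kept their direction and side of the threshold. These include values fixed by construction. Scalings shift every log2 ratio alike, which fixes list percentiles (22 values) and the cluster comparison. Unlisted miRNAs as 0 kept the scaling and so every single ratio. With at least 50 counts, none of the 8 lists that still had 3 or more tested arms crossed a percentile limit (let-7 lay at 0.45 against 0.02). The miR-15/16 family, at percentile 2.07 in the main setting, kept 2 tested arms and could not be placed. The lipid and cholesterol median (0.0832) moved from below to above that of random lists, and the cause was not tested.

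Among 86 single miRNAs, 10 log2 ratios went from above to below 0 with library totals, which lower all ratios by construction. Of these, 4 passed the test under one or both scalings, miR-191-5p (-0.0574), miR-26a-5p (-0.102), miR-148a-3p (-0.000542) and miR-194-5p (-0.154). The others were miR-107-3p (-0.139), miR-143-3p (-0.0401), miR-148a-5p (-0.0432), miR-22-5p (-0.0420), miR-29a-3p (-0.0927) and miR-29c-3p (-0.0755). miR-192-5p rose above 0 with DESeq2 (0.00596), no filter (0.0156) and at least 50 counts (0.0323), and miR-103-3p with the last 2 (0.00773 and 0.0244), none past the test. miR-30b-5p lost its call with DESeq2, no filter and at least 50 counts, and miR-28a-3p with the last 2. miR-29a-3p gained one with no filter and at least 50 counts, and miR-143-3p with at least 50 counts. With library totals 7 calls were lost and 7 gained.

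Against the main count of 58 miRNAs that differed between libraries, requiring 1.5-fold gave 22 (fewer by construction), and other settings gave 55 to 76. Of the 58, 57 passed among 57 with DESeq2, 51 among 64 with library totals, 56 among 57 with no filter, 52 among 55 with at least 50 counts and 58 among 76 with unlisted miRNAs as 0. The coefficient of variation was 0.352 with DESeq2's dispersion and 0.722 with unlisted miRNAs as 0. Pearson's r was 0.986 with a pseudocount of 10 CPM. With the total over all listed loci, miR-22-3p took 32.4% and the Sirt1 group 36.0%. The cause was not tested for these, except that a larger total lowers shares by construction.

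Leaving miR-22-3p out of the total raised every other share by construction. It gave 7.55% for hepatocyte-enriched, 7.51% for lipid and cholesterol, 11.6% for glucose and insulin, 0.971% for Ppargc1a, 3.12% for Ppara, 13.6% for let-7, 14.9% for miR-30, 0.837% for miR-29, 17.1% for miR-17/92, 0.0603% for endothelial, 0.418% for immune, 0.685% for stellate, 0.0388% for biliary and 0.0979% for Dlk1-Dio3 groups. The Sirt1 group, which lost miR-22 itself, fell to 5.63%. The other moved values were levels of single miRNAs, 14 under this total and 1 under another. Medians of the hepatocyte (-0.043), lipid (-0.131), glucose (-0.102) and miR-29 (-0.093) lists were below 0 with library totals and above 0 with TMM and DESeq2. Shares in single replicates (miR-22-3p 33.6% to 33.9%) lay within the replicate spread by construction, and 20 to 21 hairpins were dominated by 5p. Depth limits the 20 miRNAs in both libraries with under 10 counts summed, which were not tested.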

Other observations

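The tests of let-7 by shared reads, scaling and like GC content, and all tests of bases at 3' ends, were chosen after the result was seen; the straight-line GC correction and the first-base test were chosen before.

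Intronic miRNA loci held 17.2% of named counts in replicate 1 and 17.8% in replicate 2, and exonic loci, with miR-22-3p among them, held 104540 and 185192 counts. Loci listed as intergenic held 48.8% and 47.8%. Of the 44 hairpins dominated by the same arm in both libraries, 22 main arms and 6 minor arms began with U. The share was 36.4 percentage points higher in main arms (50% against 13.6%, 2-sided Fisher's exact test, p = 0.000473). That test treats arms as independent, while each main arm is paired with the minor arm of its hairpin, so the p-value is approximate. The direction is that of the hypothesis that main arms begin with U more often, as in the known preference of Argonaute for a 5' U.

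The let-7 5p arms (8) had a median log2 ratio between libraries of -0.47. All 8 lay below 0 and their summed counts gave -0.48 (also when summed over all listed loci). Reads moved among these 8 arms would leave the sum unchanged, which argues against that as the cause. A comparison of 3 scalings cannot test library composition, because each shifts every ratio alike and leaves the percentile at 0.02. After a straight-line GC correction fitted on 121 other miRNAs the median was -0.38 (bootstrap 95% interval -0.49 to -0.15). This interval treats the 8 related arms as independent and may be too narrow. Against random lists of miRNAs of like GC content the family lay at percentile 1.30, but as few as 2 such miRNAs were available for an arm, so GC content may explain part of the difference and stays open. No biological explanation was tested, because the labels give no difference between the replicates.

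In 108 hairpin sequences, each counted once and taken from replicate 2 where listed there, 135 of the 540 bases 1 to 5 after the end of the 5p arm differed from the reference, a share 72.9 times the 0.343% in the rest of the hairpin beyond them, which argues against random error or strain variants. Among differing first bases 40% were A (18 of 45, 95% interval 25.7 to 55.7), which argues against a remnant of the 3' adapter, whose first base is T, as the whole cause. U or A made up 98.5% of the 135 differing bases (75 U and 58 A). This is consistent with U and A added without template to miRNA 3' ends, a hypothesis found and tested on the same data. No biological explanation that involves a difference between samples was tested.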
